A study of Mus musculus with 8 samples.

How the data were processed

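Total RNA from RAW264.7 cells, a mouse macrophage-like line, was sequenced in 8 libraries. The cells carried either a non-silencing shRNA (shNS) or an shRNA against Dis3l2 (shDis3l2), and were grown for 4 days with doxycycline at 1 µg/mL or without it. Doxycycline is commonly used to switch on an shRNA. Samples were grouped by the labels into 4 groups: 3 shNS and 3 shDis3l2 libraries with doxycycline, and 1 library of each line without doxycycline. Nothing in the labels states that the replicates were separate cultures, so all p-values measure the spread between these samples, which may be technical.

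The libraries were made with a stranded total RNA kit that removes ribosomal RNA and were read as 150 nt pairs, per the labels' protocols. The submitters' processing notes name cutadapt, STAR 2.7 and RSEM, with the builds GRCm38 and mm10. The versions of cutadapt and RSEM, the annotation release and the strand setting of the counting are not given in the sources used here. The authors deposited 1 table of expected counts per gene, as RSEM estimates them, for 55450 genes in 8 columns, without normalization, and each column was matched to its sample by name. All 55450 gene identifiers matched GENCODE release M21, which gave the symbols, gene types and GRCm38 coordinates, and 22276 genes had a count in at least 1 library. RSEM divides reads among genes that share sequence, so values of near-identical paralogs, pseudogenes, small nuclear RNA copies and overlapping genes are estimates.

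Library totals ran from 30341823 to 45557804 counts, with 17388 to 18267 genes detected. The expected counts were rounded to whole numbers, which changed 4.68 to 5.24% of the values in a library. Genes passed edgeR's filterByExpr with a minimum count of 10, libraries were scaled by TMM, and levels are given as TMM-normalized CPM. The main test was edgeR's quasi-likelihood test with robust estimation, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 (R 4.3.3, edgeR 4.0.16). The comparison of shDis3l2 with shNS under doxycycline used the 6 doxycycline libraries and 13752 genes. The doxycycline effect in each line, and the difference between those effects, used all 8 libraries as 4 groups and 15250 genes, with 4 residual degrees of freedom. In that fit each lone library without doxycycline was assumed to vary like the others. Those 2 libraries were compared with each other by log2 ratio (prior count 2) with no test.

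Before the data were examined, 38 gene lists were also written down, and the 36 with at least 5 tested members were tested with limma's camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run as alternatives. Member counts are given over all genes tested and adjusted over the list alone. For the libraries without doxycycline, the median of a list was placed among 10000 random lists of the same size matched on mean expression. Their genes were drawn one by one, so this rank describes a value and is not a test of it.

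A group in which a gene had 0 counts was given a floor of 3 counts per library, and the fold against it is written as a lower bound. With 1 to 3 counts in a group the ratio of summed counts is given with a 95% counting interval. Intervals and floors cover counting error only. Genes named in the text are Dis3l2, then the 10 largest rises and the 10 largest falls among genes past the threshold with a mean count of at least 50, groups that did not overlap and a symbol that is not a clone or accession name, and then up to 4 members of each list with the smallest adjusted p. Where no member of a list passed, the 1 or 2 members with the smallest p stand in. Any gene outside this rule is said to have been chosen after its values were seen. The groups, tests, naming rule and most alternatives were also fixed in advance.

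The test was tried on simulated counts drawn from the real means, with 200 genes changed. The changed genes had a mean count of at least 50, and each library and gene was drawn independently, unlike real libraries in which genes move together. The rates below therefore hold for such genes and counts only. With 3 libraries against 3, it recovered 33% of genes changed 2-fold and 87% of those changed 4-fold, with 10.4% false calls among 134. For the doxycycline effect in shNS, with 3 libraries against 1, it recovered 1% and 65%, and in shDis3l2 2% and 52%. No pair of replicates agreed within counting noise, with a chi-square per gene of at least 17.3, so no library was counted as a repeat of another.

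The alternatives chosen in advance were DESeq2's size factors, library size alone, no low-count filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, all 8 libraries in the fit, removal of mitochondrial and structured RNA genes, a 2-fold minimum, and leaving out each doxycycline library in turn. After the data were seen, fits within a single line, removal of Gm26917 and Gm42418, removal of genes in a segment of chromosome 9, and doxycycline effects of lists other than the interferon-stimulated one with a library left out were added. Gm26917 held 5.36 to 7.86% of the counts and Gm42418 0.91 to 1.34%. Both are annotated as long non-coding RNAs, and they were kept in the main test. Neither lone library without doxycycline was left out of a fit, since its group would then be empty.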

Results

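Gene expression was measured by total RNA sequencing in RAW264.7 macrophage-like cells expressing a non-silencing shRNA (shNS) or an shRNA against Dis3l2 (shDis3l2). Dis3l2 encodes an exoribonuclease that degrades RNAs carrying a uridine tail. With doxycycline there were 3 libraries per line, and without it 1 library per line. The shNS libraries with doxycycline held 30341823, 35755405 and 37407688 counts in replicates 1, 2 and 3, and the shDis3l2 libraries 45557804, 33002748 and 32274120. The libraries without doxycycline held 36680298 (shNS) and 37996224 counts (shDis3l2). Protein-coding genes took 82.75 to 84.82% of the counts and mitochondrial genes 2.65 to 3.89%. The libraries separated by line along the first principal component, which held 58.5% of the variance, but this component split the shNS libraries as well. The shDis3l2 libraries lay at 56.1 to 67.1. Replicates 1 and 3 of shNS with doxycycline lay at -15.3 and -23.7, and replicate 2 and untreated shNS at -106.5 and -102.2. Within shNS, replicate 2 with doxycycline correlated more closely with the shNS library without doxycycline (r = 0.984 across genes, which are not independent) than with replicates 1 (0.939) and 3 (0.945). Replicate 1 of shNS with doxycycline correlated more closely with every shDis3l2 library (0.950 to 0.953) than with replicate 2. Replicate 3 correlated about equally with the shDis3l2 libraries (0.9425 to 0.9509) and with replicate 2.

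The targeted gene was compared first. Dis3l2 (ENSMUSG00000053333, protein coding, chromosome 1, 86703808 to 87050095, plus strand, GRCm38) fell to 48.4% of the shNS level with doxycycline, from 27.9 ± 5.54 CPM to 13.5 ± 1.46 CPM (SD, n = 3 in each group). All 3 shDis3l2 values (12, 13.5 and 14.9 CPM) lay below all 3 shNS values (33.0, 28.6 and 22.0 CPM). Without doxycycline the level was 29.6 CPM in shNS and 28.6 CPM in shDis3l2, a ratio of 0.965 (95% counting interval 0.887 to 1.05). With doxycycline the log2 fold change was -1.05 (SE 0.19, edgeR adjusted p = 0.0216), and a two-sided exact permutation test gave p = 0.10, the smallest value that 3 against 3 allows. The call was lost when shDis3l2 replicate 1, 2 or 3 was left out (edgeR adjusted p = 0.0814, 0.112 and 0.0776).

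**Figure D1:**
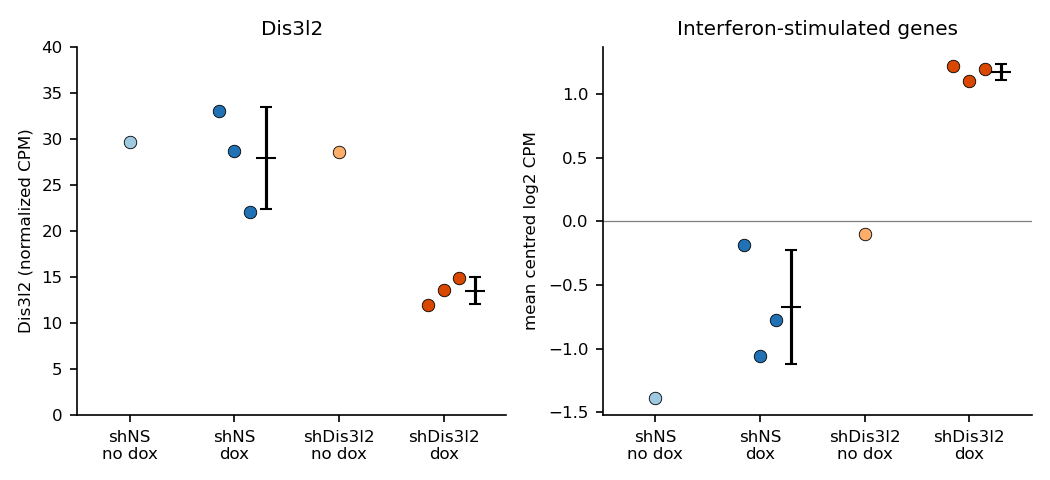
Dis3l2 level in normalized CPM (left) and the mean centred log2 CPM of the interferon-stimulated gene list (right), with 1 point per library in each group; bars give the mean ± SD of the groups with 3 libraries. Dis3l2 lies between 12 and 14.9 CPM in the shDis3l2 libraries with doxycycline and at or above 22.0 CPM elsewhere, and the interferon list is highest in those same 3 libraries, between 1.10 and 1.22.

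The main comparison set shDis3l2 against shNS under doxycycline, where Dis3l2 was lower. It also takes in any difference between the lines that was present without doxycycline. The 10 largest rises and the 10 largest falls were all seen the same way without doxycycline, in 1 library per line, as given further below. The largest differences were between a clear level in 1 line and almost none in the other. Hpgd, the enzyme that inactivates prostaglandins (ENSMUSG00000031613, chromosome 8, 56294585 to 56321043), was at 129 ± 98.7 CPM (SD, n = 3) in shDis3l2 against 1 count in the 3 shNS libraries together, a ratio of 13920 (95% counting interval 2498 to 549700). Runx3, a transcription factor of lymphoid and myeloid cells (ENSMUSG00000070691, chromosome 4, 135120652 to 135177990), rose from 0.0604 ± 0.0327 to 76.3 ± 8.81 CPM (log2 fold change 10.24, SE 0.29, edgeR adjusted p = 2.27e-05). In the other direction Kndc1 (ENSMUSG00000066129, chromosome 7, 139894696 to 139941537) stood at 110.3 ± 41.1 CPM in shNS against 3 counts in the shDis3l2 libraries together, a ratio of 4069 (1392 to 19730). Egln3, a prolyl hydroxylase that marks hypoxia-inducible factor for degradation (ENSMUSG00000035105, chromosome 12, 54178981 to 54203860), was at 24.1 ± 16.9 CPM in shNS and had no count in shDis3l2, at least 296-fold lower.

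The other large rises were Umodl1 (ratio 12350, 2216 to 487800), Pdcd1, which encodes the immune checkpoint receptor PD-1 (ratio 485, 166 to 2354), Fstl5 (log2 fold change 8.36, SE 0.64) and Rasal3, a Ras GTPase-activating protein (7.85, SE 0.38). Slc9a7, Xkr5, Cxcl11 and Chst7 had no count in shNS and were at least 255-fold, 90.2-fold, 57.3-fold and 36.4-fold higher in shDis3l2. The other large falls were Rgs18, Kif13a, Bdh1, Arrdc4, Vopp1, Adamts1 and Tfec, which had no count in shDis3l2 and were at least 93.2-fold to 161-fold lower, and Opcml (ratio 3197, 573 to 126300). Opcml lies inside the segment of chromosome 9 described last. In all, edgeR's quasi-likelihood test called 845 of 13752 genes, 293 higher and 552 lower in shDis3l2, of which 188 and 437 differed at least 2-fold. Protein-coding genes gave 258 of the rises and 516 of the falls, out of 11080 tested. Of 84 structured RNA genes 0 rose and 7 fell by this test, and in all classes together 2864 genes had an unadjusted p under 0.05, DESeq2 called 1748 genes and limma-voom 850. The count was 464, 203 and 259 without shDis3l2 replicate 1, 2 or 3, and the calls of Egln3 and Tfec were lost without shDis3l2 replicate 2 or 3, and also without shNS replicate 3 (Egln3) or replicate 1 of either line (Tfec), with an edgeR adjusted p up to 0.0863.

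Genes induced by interferon were higher in shDis3l2. Of 66 tested interferon-stimulated genes 46 rose and 1 fell (58 and 1 adjusted over the list alone), 65 had a positive fold change, and the list's median log2 fold change was 1.38 (camera adjusted p = 1.15e-51; adjusted p = 0.323 with an estimated correlation). Cxcl10, a chemokine that attracts T cells, rose from 0.232 ± 0.161 to 24.99 ± 7.77 CPM (SD, n = 3; log2 fold change 6.75, edgeR adjusted p = 0.00192). Ifit1, which binds RNA lacking a methylated cap, rose by 3.95 (adjusted p = 0.00232), Oasl2 by 3.62 and the exonuclease Isg20 by 2.99 on the log2 scale (edgeR adjusted p = 0.00356 for both). The exception was Apobec1, a cytidine deaminase, with a log2 fold change of -1.59 (edgeR adjusted p = 0.00962), named after its values were seen. These genes and the list were called in all 6 fits that left out a library, with list medians between 1.28 and 1.98. Over the 36 lists tested, 12 passed camera (7 up and 5 down), 0 with an estimated correlation (4 at an unadjusted p under 0.05) and 7 with fry.

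Related immune lists moved with it. Of 32 genes for interferon-gamma-associated GTPases and antigen presentation 10 rose and 1 fell (17 and 3 adjusted over the list alone; median 0.55, camera adjusted p = 8.13e-09, adjusted p = 0.323 with an estimated correlation). They included the GTPases Tgtp2 (log2 fold change 5.42, edgeR adjusted p = 6.75e-04), Iigp1 (4.15, adjusted p = 0.00648, from 4 counts in the shNS group) and Igtp (1.66, adjusted p = 0.00504), and Irgm1 rose from 30.3 ± 1.05 to 74.2 ± 2.25 CPM (SD, n = 3; edgeR adjusted p = 0.0020). Reads of Tgtp2 can be shared with its near-identical neighbour Tgtp1. The member that fell, named after its values were seen, was Ciita, the activator of MHC class II genes (log2 fold change -5.91, edgeR adjusted p = 0.0344). Of 46 nucleic acid sensors and adaptors 16 rose and 1 fell (19 and 3 adjusted over the list alone; median 0.31, camera adjusted p = 2.02e-07, adjusted p = 0.323 with an estimated correlation). These included Zbp1, a sensor of Z-form nucleic acid (log2 fold change 2.98), Oasl1 (2.44) and Ripk3, a kinase of necroptosis (1.74), with edgeR adjusted p between 0.00758 and 0.00913. Of the 16 that rose 12 also belong to the interferon-stimulated list, and the sensors outside that list had a median of 0.00. The sensor that fell, Tlr4 (log2 fold change -0.84, edgeR adjusted p = 0.0310), was named after its values were seen. The calls of Ciita and Tlr4 were lost without shDis3l2 replicate 1, 2 or 3, and also without shNS replicate 1 (Ciita) or without shNS replicate 2 or 3 (Tlr4), with an edgeR adjusted p up to 0.182.

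Inflammatory cytokine genes did not follow as a group. Among 43 NF-kB and cytokine genes 3 rose and 3 fell (9 and 7 adjusted over the list alone; camera adjusted p = 0.220, adjusted p = 0.950 with an estimated correlation), with a median of 0.34, a mean of -0.18 and an upward camera direction. Birc3 rose by 0.96 and Nfkb1 by 0.83 on the log2 scale (edgeR adjusted p = 0.0227 and 0.0379), as did Il18, by 1.31 (adjusted p = 0.0409), which lies in the chromosome 9 segment. Cd86, a costimulatory receptor, fell by 3.32 on the log2 scale (edgeR adjusted p = 0.0044). The other 2 that fell, named after their values were seen, were Nos2 (-5.34) and Tnfrsf9 (-6.56). The list passed without shNS replicate 2 (camera adjusted p = 0.0297) or replicate 3 (0.00697), and the calls of Birc3, Nfkb1, Il18, Nos2 and Tnfrsf9 were each lost without shDis3l2 replicate 1, 2 or 3. Nfkb1 was also lost without shNS replicate 1 or 2, Il18 without shNS replicate 2 or 3 and Nos2 without shNS replicate 3 (edgeR adjusted p up to 0.236).

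Genes of glycolysis and the hypoxia response were lower in shDis3l2. Of 34 tested 17 fell and 0 rose by edgeR (26 and 0 adjusted over the list alone), with a median of -0.94 (camera adjusted p = 5.24e-18; adjusted p = 0.323 with an estimated correlation). Bnip3, a mitophagy receptor induced by hypoxia, fell from 244 ± 65.1 to 26.4 ± 11.7 CPM (SD, n = 3; edgeR adjusted p = 0.00558). Pfkfb3, an activator of glycolysis, fell from 87.6 ± 23.2 to 21.4 ± 2.11 CPM (edgeR adjusted p = 0.00369), Ero1l, an oxidase of the endoplasmic reticulum, from 297 ± 58.1 to 88.1 ± 11.6 CPM (0.00431) and the histone demethylase Kdm3a from 77.2 ± 10.0 to 37.8 ± 2.62 CPM (0.00962). The call of Kdm3a was lost without shDis3l2 replicate 2 (edgeR adjusted p = 0.0693).

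Lists of lysosomal, macrophage and p53 target genes were also lower. Of 39 lysosome and autophagy genes 8 fell (median -0.57; camera adjusted p = 2.65e-07, adjusted p = 0.550 with an estimated correlation), among them Gla (log2 fold change -2.39), the protease Ctsb (-1.51), the autophagy enzyme Atg7 (-0.67) and Lamp1 (from 1127 to 561 CPM), and adjusted over the list alone 21 fell and 1 rose. Of 39 macrophage identity genes 9 fell and 0 rose by edgeR (12 and 3 adjusted over the list alone; median -0.42, camera adjusted p = 0.00333, adjusted p = 0.782 with an estimated correlation). The Fc receptors Fcgr3 (45.6 ± 8.10 to 15.4 ± 2.82 CPM; SD, n = 3, edgeR adjusted p = 0.00704) and Fcgr2b (log2 fold change -1.62) fell, as did the pore-forming protein Mpeg1 (-1.33), and the transcription factor Maf had no count in shDis3l2, at least 34.4-fold lower. Of 33 p53 targets 6 fell (7 adjusted over the list alone; median -0.29, camera adjusted p = 0.0255, adjusted p = 0.782 with an estimated correlation), with the death receptor Tnfrsf10b at -4.52, Phlda3 at -3.40, Trp53inp1 at -2.97 and Zmat3 at -0.95. The macrophage list missed the threshold without shNS replicate 3 (camera adjusted p = 0.0530), and the p53 list without shNS replicate 1 (0.0533) or shDis3l2 replicate 2 (0.0581) or 3 (0.0815). Of the genes named here Fcgr3 and Tnfrsf10b were called in every fit that left out a library, Gla was lost without shDis3l2 replicate 3, Phlda3 without replicate 2, and the others without either of these, with Lamp1, Mpeg1, Maf and Trp53inp1 also lost without shDis3l2 replicate 1 (edgeR adjusted p up to 0.128).

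Proliferation and histone genes were higher as lists, with few members past the test alone and with shNS replicate 1 close to the shDis3l2 libraries. The mean centred log2 level of histone genes was 0.33 in shNS replicate 1, above the 0.16 of shDis3l2 replicate 3, against -0.65 and -0.95 in shNS replicates 2 and 3. That of mitosis genes was 0.11 in shNS replicate 1, next to 0.13 in shDis3l2 replicate 1, against -0.45 and -0.72 in shNS replicates 2 and 3. Of 40 mitosis genes all had a positive fold change and 1 passed, Ccnb2 (log2 fold change 1.15, edgeR adjusted p = 0.0472; list median 0.53, camera adjusted p = 2.24e-08, adjusted p = 0.782 with an estimated correlation). Of 71 histone genes 69 had a positive fold change and 1 passed, H2afx (1.29, edgeR adjusted p = 0.0331; list median 0.74, camera adjusted p = 1.58e-12, adjusted p = 0.782 with an estimated correlation). Of 87 ribosomal protein genes 2 rose, Rps25 (0.85) and Rpl4 (0.67), with a list median of 0.15 (camera adjusted p = 0.0125, adjusted p = 0.967 with an estimated correlation). Adjusted over each list alone, 0 mitosis, 0 histone and 0 ribosomal protein genes passed by edgeR. Ccnb2, H2afx, Rps25 and Rpl4 all lie in the chromosome 9 segment, and each lost its call without shDis3l2 replicate 2 or 3 (edgeR adjusted p up to 0.176). Ccnb2, H2afx and Rpl4 also lost theirs without shDis3l2 replicate 1 or shNS replicate 2 or 3, and Rpl4 without shNS replicate 1. The ribosomal list missed the threshold without shNS replicate 1 (camera adjusted p = 0.181) or shDis3l2 replicate 1 (0.460).

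RNA decay factors and the RNA classes linked to Dis3l2 were examined next. Of 53 genes for exonucleases, the RNA exosome and uridylation 3 rose and 1 fell (4 and 1 adjusted over the list alone). These were Isg20, Rbm7 (log2 fold change 0.58, in the chromosome 9 segment) and the poly(A) polymerase Tent4a (0.69), and the exosome cofactor Mphosph6 (-0.78). The list's median of 0.11 sat at the threshold (camera adjusted p = 0.05, adjusted p = 0.552 with an estimated correlation), and without the members in the segment (Rbm7, Rexo2, Dis3l and Wdr61, chosen after the data were seen) it did not pass (0.127), nor without shNS replicate 1 (0.159) or 3 (0.0556) or shDis3l2 replicate 2 (0.0672) or 3 (0.0838). The 13 tested snoRNAs had a median of -0.92 (camera adjusted p = 0.00239, adjusted p = 0.782 with an estimated correlation), although 0 passed singly by edgeR (0 rose and 5 fell adjusted over the list alone); Snora73b was at -0.92 (edgeR adjusted p = 0.0663) and Snora74a at -1.17 (0.0690). Over the 14 snoRNAs tested with all 8 libraries, the median doxycycline effect was 0.63 in shNS and -0.05 in shDis3l2. Their median log2 ratio without doxycycline was -0.25, with 6 positive. By these values the gap with doxycycline went with a rise in shNS more than a fall in shDis3l2, resting on 1 untreated library per line. Among 22 RNAs made by RNA polymerase III and related structured RNAs 1 fell, Rnu1b1, a U1 copy whose reads can be shared with other copies (log2 fold change -3.56, edgeR adjusted p = 0.0142). That list had a median of -0.43 (camera adjusted p = 0.0529, adjusted p = 0.890 with an estimated correlation). It passed without shNS replicate 3 (camera adjusted p = 0.0225) and without shDis3l2 replicate 1 (0.0155) or 2 (0.0165), fits that all kept shDis3l2 replicate 3. Its mean centred log2 level was -0.72 in that library, against -0.07 and 0.29 in shDis3l2 replicates 1 and 2. In shNS with doxycycline the level was -0.08, 0.18 and 0.27, so 1 library carried much of the low value. The calls of Rbm7, Tent4a, Mphosph6 and Rnu1b1 were lost without shDis3l2 replicate 2 or 3 (edgeR adjusted p up to 0.197), those of Rbm7, Mphosph6 and Rnu1b1 also without replicate 1, and those of Rbm7, Tent4a and Mphosph6 without shNS replicate 2 or 3.

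Extracellular vesicle genes did not move as a list. Of 52 tested 1 rose and 1 fell, the tetraspanins Cd81 (log2 fold change 1.85, edgeR adjusted p = 0.0477) and Cd63 (-1.30, adjusted p = 0.0446), with a median of -0.06 (3 and 1 adjusted over the list alone; camera adjusted p = 0.751, adjusted p = 0.967 with an estimated correlation). Both calls were lost without shDis3l2 replicate 1, 2 or 3, and also without shNS replicate 1 (Cd81) or without shNS replicate 2 or 3 (Cd63), with an edgeR adjusted p up to 0.178. Of 33 nonsense-mediated decay genes Gadd45g rose (2.75) and Slc7a11 fell (-1.66), with a list median of 0.04 and a mean of -0.05 (camera direction down, adjusted p = 0.926). Of 47 targets of the integrated stress response Slc7a11 and the cytokine Gdf15 (2 counts in shDis3l2, ratio 83.3, 22.7 to 694) fell, with a median of 0.12 and a mean of -0.19 (camera direction up, adjusted p = 0.979, adjusted p = 0.994 with an estimated correlation). Of 43 genes of the unfolded protein response Ero1l and P4hb (-1.08) fell, with a median of -0.14 (camera adjusted p = 0.129, adjusted p = 0.967 with an estimated correlation). At the preset correlation that list passed without shNS replicate 1 (camera adjusted p = 0.0295) or 3 (0.0241) or shDis3l2 replicate 1 (0.0201), and the stress response list passed as lower without shDis3l2 replicate 1 (median -0.04, camera adjusted p = 0.0343). The calls of Gadd45g and Gdf15 were lost without shDis3l2 replicate 1, 2 or 3 and that of Gadd45g without shNS replicate 1, that of Slc7a11 without shDis3l2 replicate 1 or 3 and that of P4hb without replicate 2 (edgeR adjusted p up to 0.173).

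**Figure D2:**
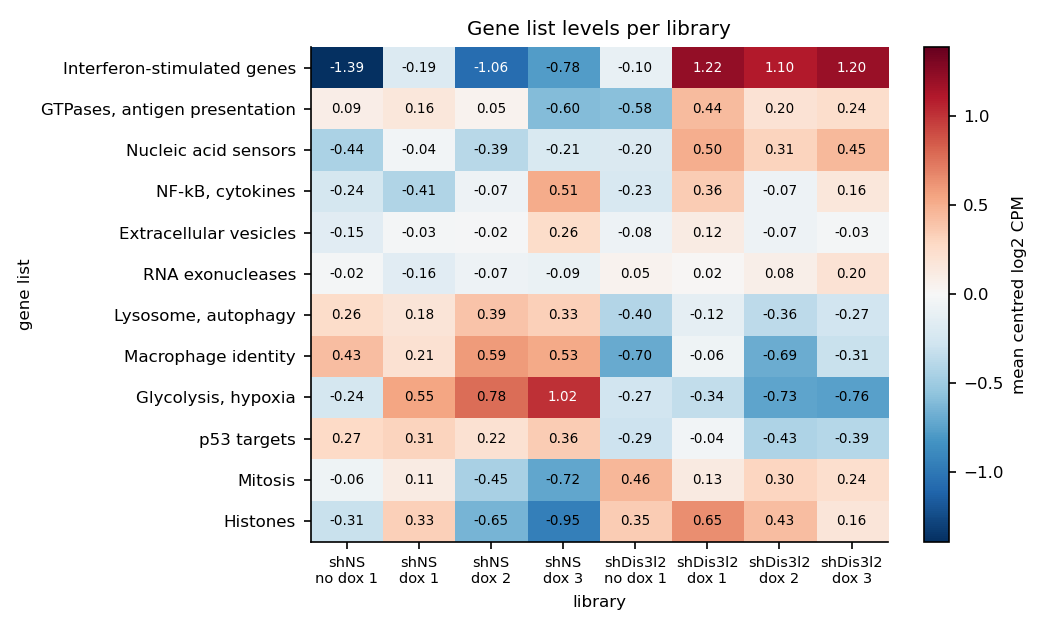
Mean centred log2 CPM of 12 gene lists (vertical axis) in each of the 8 libraries (horizontal axis), with red above and blue below the mean over libraries and the value in each cell. The interferon-stimulated list runs from -1.39 in shNS without doxycycline to 1.22 in shDis3l2 with doxycycline, and the glycolysis list is highest in shNS with doxycycline, at 0.55, 0.78 and 1.02.

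Whether the lines already differed without doxycycline was asked by setting the 2 untreated libraries against each other, with no replicate check. Hpgd (198 CPM), Umodl1 (85.5 CPM) and Rpl27-ps3 (27.1 CPM) were detected in shDis3l2 and had no count in shNS, and Runx3 (92.6 CPM) and Angptl2 (32.9 CPM) had 1. In the other direction Fn1, which encodes fibronectin, was at 1058 CPM in shNS and had no count in shDis3l2, and the same held for Cyp2b10 (673 CPM), the nuclear receptor Nr1i3 (381 CPM) and Ackr3 (199 CPM), while Chst1 was at 527 CPM against 1 count. These 5 genes did not separate the lines: with doxycycline Fn1, Cyp2b10, Nr1i3 and Ackr3 were at 697, 226, 281 and 261 CPM in shNS replicate 2 and had no count in shNS replicates 1 and 3, and Chst1 was at 484 CPM in replicate 2 against 0.598 and 0.202 CPM. Rpl27-ps3 did not separate them either, with 16.7 to 46.9 CPM in shNS with doxycycline. All 10 were chosen by the size of their ratio. At least a 2-fold ratio was seen for 3156 of 15250 genes, 1417 higher and 1739 lower in shDis3l2. The interferon-stimulated list had a median log2 ratio of 0.63, above all of the 10000 random lists, with 56 of 67 members positive. Histone (0.61), mitosis (0.49) and zinc finger genes (0.18) were above all random lists as well, and the unfolded protein response (-0.81), lysosome (-0.51), S phase (-0.48), integrated stress response (-0.44) and cholesterol (-0.43) lists were below all of them. These ranks cover neither the spread between libraries nor the shared movement of list members. With doxycycline the estimated correlation was 0.34 in the interferon-stimulated, 0.73 in the mitosis and 0.85 in the histone list. Within shNS with doxycycline the mean centred log2 level of histone genes ran from -0.95 to 0.33. A rank past all random lists is therefore no evidence of a difference between the lines beyond that spread. The GTPase and antigen presentation list had a median of -0.03 and the glycolysis list 0.16.

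Genes that differed with doxycycline mostly differed the same way without it. Of the 845 called genes 788 (93.3%) had the same sign, against 66.8% of the 12907 genes not called. The exact 95% interval of that share, 91.4 to 94.8, treats the genes as independent, which they are not, and leaves out the spread between libraries. With a doxycycline library left out the share ran from 84.7 to 95.6%, past both ends of the interval. It was lowest without shNS replicate 2, the library closest to untreated shNS. The genes not called were not matched on the size of their difference, so part of the gap to their 66.8% was built in. Calls made with shNS replicate 2 also underlie the 2-fold share given next. Of the 625 called genes with at least a 2-fold difference 449 (71.8%) also differed at least 2-fold the same way without doxycycline. Hpgd, Umodl1, Runx3 and Kndc1 were among these, with Kndc1 at 76.8 CPM in shNS and no count in shDis3l2 without doxycycline. The other large rises had log2 ratios without doxycycline of 1.90 (Cxcl11) to 8.32 (Slc9a7), and the other large falls -5.59 (Opcml) to -8.48 (Rgs18). With limits of 5 and 0.1 CPM, chosen after the data were seen, 10 genes were high in all 4 shNS libraries and low in all 4 shDis3l2 libraries. The reverse held for 7. In contrast, the log2 ratio was -0.05 for Dis3l2 itself and 0.41 for Bnip3. Cxcl10 had a log2 ratio of 3.87 without doxycycline against 6.75 with it, and Zbp1 0.02 against 2.98. Across the called genes r was 0.907 between the log2 values with and without doxycycline, over genes that are not independent.

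**Figure D3:**
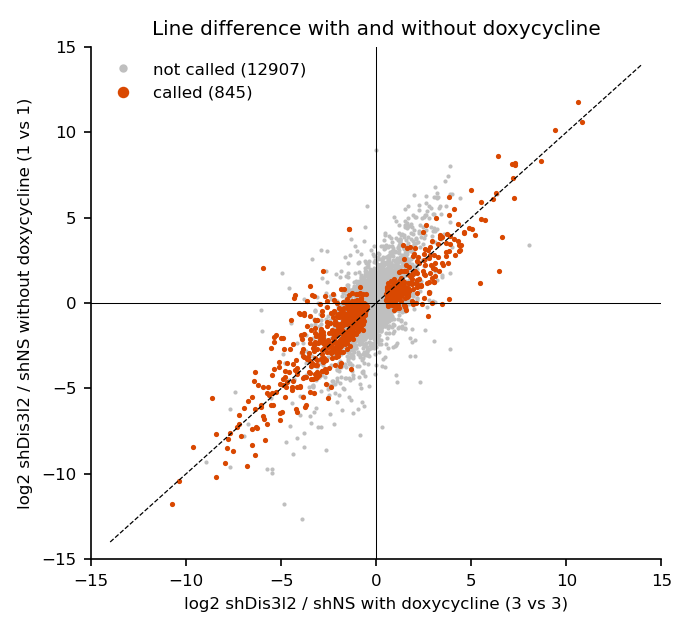
Log2 ratio of shDis3l2 to shNS with doxycycline (horizontal axis, 3 against 3 libraries) and without it (vertical axis, 1 against 1) for the 845 called genes (orange) and 12907 genes not called (grey), with the dashed line marking equal values. Most called genes lie in the same quadrant in both conditions, 788 of 845.

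The effect of doxycycline in shNS cells asked what the drug and a non-silencing shRNA do. No gene passed: edgeR called 0 of 15250, with 646 at an unadjusted p under 0.05 and a lowest adjusted p of 0.146. DESeq2 called 72 genes (61 up and 11 down), of which 3 that rose are interferon-stimulated genes, and limma-voom called 1. Leaving out shNS replicate 2 with doxycycline, the library closest to the untreated one, gave 544 calls by edgeR (252 up and 292 down), against 0 without each of the other 5. That fit sets replicates 1 and 3 against an untreated library that also differed from them in genes such as Fn1, at 1058 CPM untreated and 697 CPM in replicate 2 with no count in replicates 1 and 3. With limits of 5 and 0.1 CPM, chosen after the data were seen, 23 genes were high in replicate 2 and the untreated library and near absent in replicates 1 and 3, and 1 gene was the reverse. Doxycycline and this difference among the shNS libraries are confounded in that fit. As a list, glycolysis and hypoxia genes had a median of 0.80 (33 of 35 positive; camera adjusted p = 3.45e-22, adjusted p = 0.935 with an estimated correlation), and interferon-stimulated genes 0.72 (58 of 67 positive; camera adjusted p = 4.15e-13, adjusted p = 0.935 with an estimated correlation), or 0.45 without shNS replicate 1. Of the 36 lists 7 passed camera, and 0 with an estimated correlation.

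In shDis3l2 cells the same comparison spans the fall of Dis3l2. The interferon-stimulated list had a median of 1.19, with 65 of 67 members positive (camera adjusted p = 2.72e-64, adjusted p = 0.144 with an estimated correlation), and the GTPase and antigen presentation list a median of 0.95, with 31 of 34 positive (camera adjusted p = 5.69e-22, adjusted p = 0.0990 with an estimated correlation). Cxcl10 was at 4.75 CPM without doxycycline and 24.99 ± 7.77 CPM (SD, n = 3) with it, and Zbp1 had a log2 fold change of 2.57, but no single gene passed. By edgeR 0 of 15250 genes were called, with 504 at an unadjusted p under 0.05 and a lowest adjusted p of 0.804, while limma-voom called 0 and DESeq2 called 64 (49 up and 15 down), of which 16 that rose are interferon-stimulated genes. Dis3l2 had a log2 fold change of -1.09 and did not pass after adjustment over all 15250 genes. It was at 28.6 CPM in the 1 library without doxycycline and at 12, 13.5 and 14.9 CPM with it. With the spread taken from the 4 shDis3l2 libraries alone, 1 gene passed, Angptl4, an inhibitor of lipoprotein lipase (log2 fold change 4.45, edgeR adjusted p = 0.0355), named after its value was seen. Of the 36 lists 20 passed camera, and 0 with an estimated correlation.

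Each shRNA was in 1 line only, and the lines also differed without doxycycline. A response to the shRNA therefore cannot be told apart from a different doxycycline response of the line. The difference between the 2 doxycycline effects asks only whether the response differs between the lines. The median of this difference, with shNS subtracted from shDis3l2, was 0.56 for the interferon-stimulated list (camera adjusted p = 7.11e-08, adjusted p = 0.613 with an estimated correlation), 0.83 for the GTPase and antigen presentation list (camera adjusted p = 8.22e-10, adjusted p = 0.377 with an estimated correlation) and -1.05 for the glycolysis and hypoxia list (camera adjusted p = 1.06e-26, adjusted p = 0.377 with an estimated correlation). The shNS libraries did not move alike in the interferon-stimulated list, whose mean centred log2 level was -1.39 without doxycycline and -0.19, -1.06 and -0.78 in replicates 1, 2 and 3 with it, against -0.10 and 1.22, 1.10 and 1.20 in shDis3l2. The rise in shNS replicate 1 was thus close to that in shDis3l2. No gene passed by edgeR (0 of 15250, 577 at an unadjusted p under 0.05, lowest adjusted p 0.243), DESeq2 called 34 genes (9 up and 25 down), none of them interferon-stimulated, and limma-voom 0. Without shNS replicate 2 with doxycycline edgeR called 121 genes (52 up and 69 down), in a fit with the same confounding. Dis3l2 itself was at -0.997 and did not pass after adjustment over all 15250 genes.

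A run of neighbouring genes on chromosome 9 was higher in shDis3l2, seen only when the fold changes were laid out by position and therefore chosen after the data were seen, as were its window size and limits. Between 25481547 and 83409660 (GRCm38) the 240 well expressed genes had a median log2 ratio of 0.52 (quartiles 0.25 to 0.68; 87.5% positive), against -0.04 for the 264 other such genes of chromosome 9. The segment's median was 0.50 without doxycycline and 0.51 with it. In the 4 shDis3l2 libraries it ran from 0.502 to 0.537 and in the 4 shNS libraries from -0.04 to 0.03. It spanned a run of 11 windows past the limit, against a longest run of 3 in any other of the 35 splits of the 8 libraries into groups of 4. Every other split puts libraries of both lines in each group, which dilutes the shift, and the segment was drawn from the real split. The shorter runs were therefore built in, and this contrast is no test of the segment. The segment held 61 of the 293 genes that rose (20.8%) and 2.54% of the genes tested, a share with no test since the segment was drawn from the same log2 ratios, including Ccnb2, H2afx, Il18, Rbm7, Cox5a, Cox7a2, Rps25 and Rpl4. It held 5 of the 552 that fell, Opcml, Gm6166 and, named after their values were seen, Scamp5, Fxyd2 and Aph1c, and no member of the interferon-stimulated list.

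**Figure D4:**
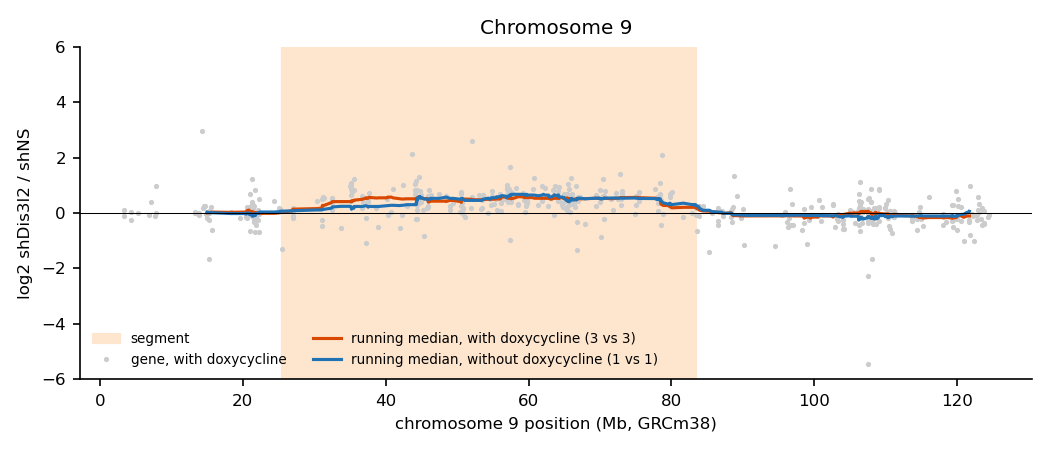
Log2 ratio of shDis3l2 to shNS for genes along chromosome 9 (horizontal axis, Mb, GRCm38), with grey points for single genes with doxycycline and lines for running medians of 40 genes with doxycycline (orange, 3 against 3 libraries) and without it (blue, 1 against 1). The shaded segment from 25.5 to 83.4 Mb is shifted in both conditions, by medians of 0.51 and 0.50.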

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

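The 14 results in this part were picked by a test of the difference between the doxycycline effects of the 2 lines, which was fixed before the data were examined. Except for the interferon-stimulated list, the tests with a doxycycline library left out were chosen after these results were seen. Each value is the median log2 difference of a gene list, with the doxycycline effect in shNS subtracted from that in shDis3l2. All rest on camera with the preset correlation, and with an estimated correlation 0 of the 36 lists passed (lowest adjusted p 0.377). Each line had 1 library without doxycycline, and groups of 3 libraries or fewer were not searched for samples far from the others.

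Among immune and stress lists the difference was 0.83 for interferon-gamma-associated GTPases and antigen presentation, 0.56 for interferon-stimulated genes, 0.27 for nucleic acid sensors and 0.17 for apoptosis and pyroptosis genes, a list that did not pass without shNS replicate 1 (camera adjusted p = 0.105) or 2 (0.114). It was 0.50 for the unfolded protein response and 0.65 for targets of the integrated stress response, where shDis3l2 replicate 1 carried much of it, with 0.39 left without that library. The interferon-stimulated list rose in shNS replicate 1 about as in shDis3l2, from a mean centred log2 level of -1.39 to -0.19 against -0.10 to between 1.10 and 1.22. The stress lists rest on the single untreated library of each line, at levels of -0.56 and -0.59 in shDis3l2 and 0.33 and 0.34 in shNS. For doxycycline in shNS their medians were -0.22 and -0.19, and in shDis3l2 0.35 and 0.47. Replicate 2 of shNS with doxycycline was at 0.45 for the unfolded protein response, above untreated shNS. Without doxycycline the median in shDis3l2 relative to shNS was -0.81 for the unfolded protein response and -0.44 for the integrated stress response. With doxycycline these were -0.14 and 0.12, the latter at -0.04 without shDis3l2 replicate 1.

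Among growth and mitochondrial lists the difference was 0.57 for S phase genes, 0.20 for mitochondrial ribosomal proteins and 0.19 for nuclear respiratory chain subunits. Neither mitochondrial list passed without shDis3l2 replicate 1 or without shNS replicate 1. Without shDis3l2 replicate 1 the ribosomal proteins were at 0.08 (camera adjusted p = 0.110) and the respiratory chain at 0.13 (0.128), and without shNS replicate 1 they were at 0.12 (0.113) and 0.20 (0.0679). Lists with a difference below 0 were glycolysis and hypoxia (-1.05), snoRNAs (-0.76), structured RNAs made by RNA polymerase III and related (-0.51), zinc finger genes (-0.18) and predicted genes (-0.18). The structured RNA list was at -0.31 without shDis3l2 replicate 3 and -0.32 without shNS replicate 3, past the test in both, and the predicted genes did not pass without shNS replicate 1 (-0.02, camera adjusted p = 0.499) or shDis3l2 replicate 1 (-0.04, 0.297). The glycolysis list had a median of 0.80 for doxycycline in shNS and -0.21 in shDis3l2, and the S phase list -0.18 (-0.30 without shNS replicate 3, and not past the test without shNS replicate 2, camera adjusted p = 0.271) and 0.38. Relative to shNS, the S phase list in shDis3l2 was at -0.48 without doxycycline and at 0.10 with it. The first value came from 1 library per line. Its rank below all of the 10000 random lists does not cover the spread between libraries.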

How the results depend on the processing

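Fits within 1 line, removal of Gm26917 and Gm42418, removal of the chromosome 9 segment and doxycycline effects of lists other than the interferon-stimulated one with a library left out were tests chosen after the results were seen; the other alternatives were not. None of the 845 genes called changed sign in any of the alternatives that refitted the comparison of shDis3l2 with shNS under doxycycline. Of 97 named genes past the test 41 were called in all 6 fits with a library left out. The cause of the changes was not tested.

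For that comparison DESeq2 called 1748 genes (839 of the 845 among them), and the counts with a library left out ran from 203 (without shDis3l2 replicate 2) to 1157 (without shNS replicate 1). The log2 fold change of Dis3l2 ran from -1.20 to -0.88, and the number of lists from 10 to 17. Over lists, camera with an estimated correlation gave 0 and fry 7. The integrated stress response list, with a median of 0.12, was called as lower without shDis3l2 replicate 1 (median -0.0395), and its medians with a library left out reached 0.21. The exonuclease list was lost with DESeq2's size factors (camera adjusted p = 0.0527), the stricter filter (0.0574) and without Gm26917 and Gm42418 (0.0506), and the snoRNA list without a low-count filter (0.0743). The structured RNA list passed with library size alone (0.0446). The same-sign share without doxycycline ran from 84.7% (without shNS replicate 2) to 95.6% (without shDis3l2 replicate 2).

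For the doxycycline effects edgeR called 0 genes (646 in shNS, 504 in shDis3l2 and 577 for the difference at an unadjusted p under 0.05). DESeq2 called 72 in shNS, 64 in shDis3l2 and 34 for the difference. Without a low-count filter 2 genes, Gm23444 and Gm23472, passed in shNS and the same 2 for the difference; limma-voom called 1 in shNS, Cacna1g; and the spread of the shDis3l2 line alone gave 1, Angptl4. These were named after their values were seen. With a library left out the counts ran from 0 to 544 in shNS and from 0 to 121 for the difference, both highest without shNS replicate 2, and were 0 in shDis3l2.

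With the replicate number as a block 421 genes were called (389 shared with the 845) and Dis3l2 had a log2 fold change of -1.03 (edgeR adjusted p = 0.0822). The numbers did not pair the samples, since deviations of libraries with the same number correlated at -0.122, 0.0208 and -0.00601. Lists changed too, with the exonuclease list lost (camera adjusted p = 0.0704) and the structured RNA (0.0452) and cholesterol (0.0174) lists gained. Depth limits the folds of genes with no count in a line to their lower bounds.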

Other observations

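The tests of explanations for the 3 patterns weighed (except the 2 counts of splits), the removal of the chromosome 9 segment and the limits of 5 and 0.1 CPM were chosen after the results were seen. Several lists outside the main comparisons held single genes that differed between shDis3l2 and shNS under doxycycline. Of 19 heat shock and oxidative stress genes 3 fell, Slc7a11, the haem transporter Slc48a1 (log2 fold change -1.63) and Hmox1, which degrades haem (-2.78). That list had a median of -0.14 (camera adjusted p = 0.129, 0.950 with an estimated correlation) and at the preset correlation passed without shNS replicate 1 (2.7e-05) or without the chromosome 9 segment (0.0441). Of 13 growth genes linked to let-7 or Dis3l2 the receptor Igf2r (-3.62) and the secreted growth factor Igf1 (-5.42) fell (camera adjusted p = 0.365). Of 14 lipid efflux genes the lipid droplet protein Plin2 fell (-2.46; camera adjusted p = 0.237), and of 14 long non-coding RNAs Malat1 fell from 20140 ± 6345 to 6927 ± 2106 CPM (SD, n = 3; edgeR adjusted p = 0.0376), the list having a median of 0.01, a mean of -0.36 and a camera adjusted p of 0.716. The calls of Slc48a1, Hmox1, Igf2r, Igf1, Plin2 and Malat1 were each lost without shDis3l2 replicate 2 (edgeR adjusted p up to 0.214) and without at least 1 other library. Cholesterol synthesis genes (27, median -0.34, camera adjusted p = 0.133, 0.967 with an estimated correlation) had no member past edgeR's test, with Hmgcs1 at -0.98 (adjusted p = 0.185) and Nsdhl at -0.59 (0.269), and at the preset correlation the list passed without shDis3l2 replicate 1 (9.5e-08).

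Mitochondrial lists held few calls. Among 63 nuclear respiratory chain genes Cox5a (0.67) and Cox7a2 (0.71), both in the chromosome 9 segment, rose and Ndufv3 (-0.78) fell, with a median of -0.02 and an upward camera direction (adjusted p = 0.926). Mrpl54 (0.75) rose and Mrpl45 (-0.48) fell among 78 mitochondrial ribosomal proteins (camera adjusted p = 0.673), Lonp1 (-0.69) fell among 16 genes of the mitochondrial unfolded protein response (0.289), and mt-Nd6 (-0.55) among 13 mitochondrially encoded genes (0.673, and 0.967 with an estimated correlation), a list that at the preset correlation passed without shDis3l2 replicate 1 (0.0196). All 7 of these calls were lost without shDis3l2 replicate 2 (edgeR adjusted p up to 0.266) and without other libraries. Of 343 zinc finger genes 4 rose and 10 fell, led by Zfp90 (-3.15), Zfp462 (-6.22) and Zfp870 (-1.46), with Zfp133-ps at least 4.49-fold lower (median 0.01, mean -0.10, camera adjusted p = 0.964). Of 1992 predicted genes 19 rose and 23 fell (camera adjusted p = 0.478, 0.0201 without shDis3l2 replicate 1, and 0.967 with an estimated correlation), among them Gm16316 (-10.82), Gm25939 (-3.11), Gm6166 (-5.17) and Gm45540, at least 90.7-fold higher, which lies inside Hpgd on the same strand. Birc3 rose among 28 apoptosis genes (camera adjusted p = 0.133). The calls of Zfp462, Zfp870 and Zfp133-ps were lost without shDis3l2 replicate 2 (edgeR adjusted p up to 0.0715), and that of Zfp133-ps also without replicates 1 and 3.

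Markers of other cell types gave single calls. Siglech was at least 7.43-fold higher in shDis3l2 among 8 dendritic cell markers (median -0.15, mean 0.55, camera adjusted p = 0.673), Ctsk fell by 6.18 on the log2 scale among 15 osteoclast markers (camera adjusted p = 0.639), and of 2 measured lymphocyte markers Ighm rose by 3.74, while Pdgfrb, the 1 fibroblast or epithelial marker that passed the filter of the 6 doxycycline libraries, was at 1.02 (edgeR adjusted p = 0.454). With Fn1, which passed the filter of the 8 libraries, that list stood at a mean centred log2 level of 4.22 in shNS replicate 2 with doxycycline and 4.13 in shNS without it, against -1.92 to -1.03 in the other 6. The calls of Siglech, Ctsk and Ighm were lost without shDis3l2 replicate 2 (edgeR adjusted p up to 0.169) and without other libraries. No member passed edgeR's test among 43 S phase genes (Gins3 at -0.66 and Tyms at 0.44; camera adjusted p = 0.201, 0.0474 without shNS replicate 3, and 0.950 with an estimated correlation), 25 calcium-handling genes (Vdac1 at -0.45 and Itpr3 at 0.47; median -0.05, mean 0.03, camera adjusted p = 0.895), 12 snoRNA host genes (Snhg5 at -0.33 and Gas5 at -0.40; 0.361) and 5 microRNA genes (Mir22hg at -0.98 and Mir17hg at 0.31; 0.926). With 5 and 0.1 CPM as limits chosen after the data were seen, 17 genes, Fn1, Cyp2b10, Nr1i3 and Ackr3 among them, were above the first in shNS replicate 2 with doxycycline and in shNS without it and below the second in the other 6 libraries.

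The first pattern weighed is the number of genes that differed with doxycycline. Of the called genes with at least a 2-fold difference 71.8% also differed at least 2-fold the same way without doxycycline, so a difference between the lines that was present before the treatment is a candidate explanation for most of them, as a hypothesis resting on 1 library per line. A knockdown that leaks without doxycycline stays open, since the Dis3l2 ratio of 0.965 had an interval that includes 1 but came from a single pair of libraries. Of the 10 splits of the 6 libraries, 1, the real one, gave as many calls, with 845 against a highest other of 0, and 10 splits are too few for a share under 0.05. Every other split also puts libraries of both lines in each group, so the line difference adds to the spread within groups. Fewer calls in those splits were therefore built in, and this contrast is no test of the number of calls.

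The second pattern is the higher interferon-stimulated genes in shDis3l2. A single library as the source is argued against by the lowest median with a library left out, 1.28. The list was already higher without doxycycline, with a median of 0.63, so a difference between the lines may account for part of it, and the test of the difference between the doxycycline effects did not pass with an estimated correlation (adjusted p = 0.613), so a response to the knockdown and a prior difference cannot be told apart with 1 untreated library per line. Counting the real one, 9 of the 10 splits gave at least the real 12 called lists, with a highest other of 21, so the number of lists does not set the real split apart, and 10 splits cannot give a share under 0.05. Every other split sets 2 libraries of a line against 1 and so keeps part of the real difference, which leaves the median of the interferon list, 1.38 in the real split and at most 0.713 in the others, without a null to be set against; camera with the preset correlation called that list in all 9 others too (adjusted p up to 0.00337, against 1.15e-51).

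The third pattern is the chromosome 9 segment. Normalization scales a whole library, and is argued against by the medians of whole chromosomes. The largest shift of any other chromosome or of the rest of chromosome 9 was 0.05 (0.0529) on the log2 scale. In windows of 40 genes, the measure that drew the segment, shifts outside it reached 0.25, on chromosome 17. Inside it they ran from 0.40 to 0.60. A response to the knockdown would leave the segment unshifted without doxycycline, where its median was 0.50 (0.502), but that is 1 library per line. A difference in copy number between the lines may account for it. Genes of low, middle and high expression all shifted, by at least 0.49 (0.488), against 0.58 for a change from 2 to 3 copies. The segment was drawn from these same log2 ratios, so a shift of its genes was built in. The 3 expression classes only describe how even that shift was. Copy number was not measured, and a gain in shDis3l2 was not told apart from a loss in shNS.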
